A study of Mus musculus with 16 samples.

How the data were processed

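Bulk RNA-seq was made from the cranial and the caudal mesonephros of XX mouse embryos at embryonic day 16.5. The mesonephros is the embryonic structure that holds the Wolffian and Müllerian ducts, the primordia of the male and female reproductive tracts. Per the labels, control embryos carried Osr2Cre/+;Gata2 f/+ and conditional knockout (cKO) embryos Osr2Cre/+;Gata2 f/f, so both genotypes carried the Cre and the control kept a floxed allele over a wild-type allele. Each of the 4 groups had 4 libraries, and groups and replicate numbers were taken from the sample titles. The design text states 3 samples per region and group, and the labels do not explain the difference. The labels do not say whether the libraries of a group came from separate embryos, nor which cranial and caudal libraries came from 1 embryo. Libraries were therefore taken as independent, and p-values measure only the spread between these libraries. Per the labels' protocols, total RNA was extracted with a column kit for small samples, mRNA was captured on poly-T beads, and cDNA was primed with random hexamers. The protocols do not state whether the libraries keep the strand.

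The submitters' processing notes name fastp 0.23.4, FastQC 0.12.1, STAR 2.7.11b, featureCounts 2.0.6, DESeq2 1.42.0 and the mouse build mm39, without settings or order. One deposited table per region holds whole-number counts per gene, not normalized, per the file headers. The same deposited tables hold TPM columns, which equal the counts over gene length scaled to 1e6 per library, and columns without a unit in their header whose values equal FPKM by the authors' gene lengths. They also hold the authors' DESeq2 columns: a mean signal of counts over size factors, a log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value. For the caudal region a count table with gene lengths and a summary of read assignment were deposited too, and the counts in both caudal tables were identical. A deposited list of names per region, with no values, completed the set. The counts were the input of every test below. The TPM and FPKM columns were used only to check the units, and the sample information of the caudal region was not used because its replicate order differs from the titles. Coordinates are those of the deposited tables in mm39. A reference genome of another build was not used here.

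The tables list 57010 genes, of which 710 have no symbol. Every count column was tied to 1 sample by its library name. Totals ran from 22.8 to 49.8 M counts per library. Reads were assigned to genes for 73.6% to 77.4% of the caudal alignments, and no such summary was used for the cranial region. Replicates were compared by a chi-square test of their counts over genes with at least 20 counts in the pair. Chi-square over its degrees of freedom lay between 8.14 and 343, so no pair was as alike as copies of 1 library would be. No library was left out of the main tests. Counts of the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were 0 except for 8 counts of Uty in cranial cKO 3. The list that holds them with Xist had fewer than 3 testable genes and was not tested.

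R 4.3.3 was used with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (1.17.8). The main test was the quasi-likelihood test of edgeR (glmQLFit, glmQLFTest) with TMM scaling, genes kept by filterByExpr, and Benjamini-Hochberg adjustment (FDR) at 0.05. The cranial and the caudal libraries were each fitted alone for the comparison of genotypes. The interaction of region and genotype, and the comparison of regions within a genotype, came from 1 fit of all 16 libraries with a mean per group. Log2 fold changes carry the prior count of edgeR and are given ± their standard error. Levels are TMM-scaled counts per 1e6 (CPM), given as mean ± SD over 4 libraries. Intervals of ratios near 0 counts are exact 95% intervals that cover counting error only, and a group with 0 counts was set to a floor of 3 counts over the group.

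The design, the named genes, the gene lists and the alternatives were fixed before the data were examined. The text names Gata2; up to 10 genes higher and 10 lower by absolute log2 fold change among genes past the FDR with a mean log2 CPM of at least 0 and every cKO library on one side of every control library; up to 4 members past the FDR per list; and up to 3 members with the smallest p from the lists on GATA factors, duct epithelium, Müllerian duct, Wolffian duct and duct mesenchyme. The interaction has up to 5 genes each way, and the region comparison up to 10 each way plus Hox and duct genes. Predicted gene models were counted but not named, and results of 3 genes that the rule takes are not reported here. Genes named outside this rule were chosen after their values were seen, and the text says so. The 38 lists hold 518 genes, of which 2 have no entry in the tables. They cover GATA factors, duct epithelium, Müllerian and Wolffian duct, duct mesenchyme, AMH response, sex steroid receptors, Wnt, Hedgehog, BMP, FGF and retinoic acid signalling, 2 groups of Hox genes, extracellular matrix, cell cycle, p53, stress programmes, genes beside Gata2, and markers of other cell types that a dissected mesonephros could hold. Lists were tested with camera of limma on log2 CPM (prior count 2) at a preset correlation of 0.01, with adjustment over lists, and again with the correlation estimated per list and with fry. Members were counted by the FDR over all genes and by p-values adjusted over the list alone. Several lists share members.

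Alternatives were DESeq2 size factors, no filter and a filter of CPM 1 in 4 libraries, the DESeq2 Wald test, limma-voom with sample quality weights, the replicate number as a block, 1 fit of all libraries, other thresholds, and each library left out in turn. Added after seeing the data were fits within libraries of like 18S rRNA content and fits with that content, above or below 5% of counts, as a term, and the alternatives of lists for the interaction and for the regions in controls. The steps were tested on simulated counts drawn from the means and library sizes of each comparison, with 200 genes changed. In the cranial simulation over 19455 genes, 35.8% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 60.6% of those changed 3-fold were recovered. In the caudal simulation over 18199 genes these shares were 38.8%, 62.7% and 72.7%. For the interaction over 21252 genes they were 11.9%, 25.4% and 53.0%. Of the calls in the 5 simulated comparisons, 3.96% to 7.94% were unchanged genes. The simulated counts were drawn independently around 1 mean per gene, apart from the changed genes, and held no groups of 18S rRNA content. These shares therefore do not cover such a structure of the real libraries. Other splits of the libraries were refitted for each comparison, all 35 where the groups had 4 libraries each and 100 drawn with a fixed seed for the interaction.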

Results

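RNA was sequenced from the cranial and the caudal mesonephros of XX mouse embryos at E16.5, in control embryos (Osr2Cre/+;Gata2 f/+) and in embryos labelled Gata2 cKO (Osr2Cre/+;Gata2 f/f). Gata2 is a zinc finger transcription factor, and the series asks what it does for the Müllerian duct at its cranial end. Each of the 4 groups held 4 libraries. Total counts per library were 26.7 to 49.8 M in cranial controls, 22.8 to 33.5 M in cranial cKO libraries, 33.2 to 36.9 M in caudal controls and 30.6 to 37.2 M in caudal cKO libraries. The cranial libraries differed in 18S rRNA (Rn18s-rs5), which held 11.1% to 17.1% of the counts in cranial controls 1 and 2 and all 4 cranial cKO libraries. It held 0.712% and 1.07% in cranial controls 3 and 4, which were also the deepest libraries (47.9 and 49.8 M), and 0.345% to 3.18% in the 8 caudal libraries. Between cranial controls 1 and 2 on one side and 3 and 4 on the other, 3429 of 20368 genes passed an FDR of 0.05. Cranial changes are therefore given over all 8 libraries and again within the 6 libraries of high 18S rRNA (here the high-rRNA libraries), a comparison of 2 controls with 4 cKO libraries chosen after seeing the data. Changes below are log2 fold changes of labelled cKO over control ± SE from edgeR's quasi-likelihood test, and levels are counts per 1e6 (CPM) as mean ± SD with n = 4. Where a bracket adds a second change after "and", that is the change within the high-rRNA libraries.

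**Figure D1:**
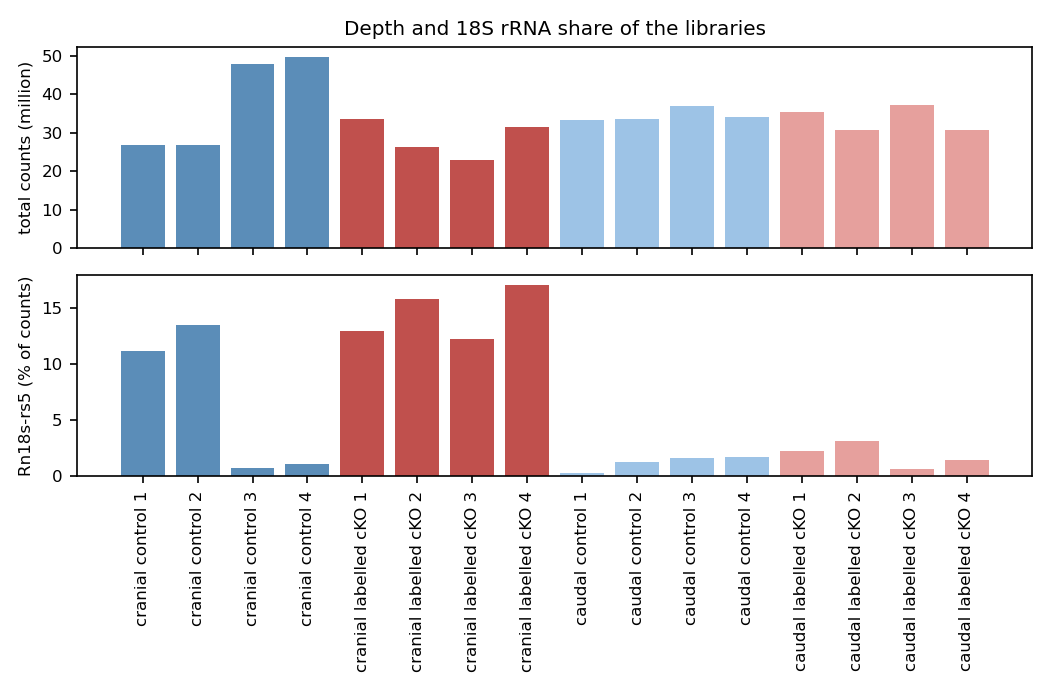
Total counts (upper, M = 1e6, bars) and the percentage of counts from the 18S rRNA gene Rn18s-rs5 (lower bars) in each of the 16 libraries, coloured by group. Cranial controls 3 and 4 hold 0.712% and 1.07% of 18S rRNA counts and the other 6 cranial libraries 11.1% to 17.1%.

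Gata2 (ENSMUSG00000015053, chromosome 6, 88170873 to 88184014 on the plus strand in mm39) was counted over the whole gene. In the cranial controls its level was 293, 320, 390 and 372 CPM, and in the cranial cKO libraries 304, 307, 306 and 281 CPM. These levels did not differ past the threshold (−0.14 ± 0.07, FDR 0.264), nor within the high-rRNA libraries (−0.04 ± 0.07, FDR 0.845). In the caudal controls the level was 499, 473, 496 and 506 CPM, and in the caudal cKO libraries 755, 727, 723 and 639 CPM, a rise with the cKO label (0.53 ± 0.08, FDR 5.65e-04). The authors' deposited table gives −0.14 (adjusted p 0.169) for the cranial region and 0.53 (adjusted p 5.28e-09) for the caudal region. Counts over a whole gene include exons outside a floxed part and its altered transcripts, and the floxed exons are not given in the sources used here. Gata2 counts therefore do not check the genotype labels, and every direction below rests on the labels as given.

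In the cranial mesonephros 2140 of 19455 tested genes changed with the cKO label, 952 upward and 1188 downward, and 204 of them changed at least 2-fold. Osr2, a zinc finger gene of urogenital mesenchyme whose locus drives the Cre in both genotypes, fell from 174 ± 30.7 to 45.9 ± 1.39 CPM (−1.86 ± 0.09, FDR 2.09e-06, and −1.69 within the high-rRNA libraries). Wnt6, a secreted Wnt ligand, fell from 67.3 ± 13.7 to 15.8 ± 1.18 CPM (−2.02 ± 0.12, FDR 5.82e-06, and −1.84). Foxl2, a forkhead transcription factor, fell from 27.2 ± 6.63 to 6.55 ± 0.706 CPM (−2.00 ± 0.16, FDR 3.72e-05, and −1.91). The BMP antagonist Nog fell from 20.5 ± 2.36 to 4.14 ± 2.05 CPM (−2.23 ± 0.28, FDR 7.48e-04, and −2.15). Shox2, a homeobox gene, rose from 0.121 ± 0.109 to 12.9 ± 3.73 CPM (6.57 ± 0.44, FDR 1.07e-05). Cranial controls 1 and 2 held 2 and 0 counts of it, so no fold is given within the high-rRNA libraries (FDR 1.21e-12 there). The matricellular gene Ccn3 rose from 5.79 ± 0.786 to 45.5 ± 5.49 CPM (3.04 ± 0.13, FDR 6.4e-07, and 2.92 within the high-rRNA libraries).

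The other rising genes of the naming rule were the kynurenine pathway enzyme Kynu (4.83 ± 0.59, and 5.05 within the high-rRNA libraries), the oxytocin receptor Oxtr (2.85 ± 0.34 and 2.85), Lrrc55 (2.59 ± 0.32 and 2.77), the Wnt antagonist Wif1 (2.35 ± 0.47 and 2.41) and the teneurin Tenm1 (2.15 ± 0.31 and 1.98). Smaller rises were those of the potassium channel Kcnh5 (2.12 ± 0.60 and 1.88), Sostdc1, a secreted antagonist of Wnt and BMP (1.94 ± 0.12 and 2.18), and St6galnac5 (1.92 ± 0.34 and 1.66). The other falling genes were the metallothionein Mt3 (−4.08 ± 0.64 and −3.91), the cation exchanger Slc24a2 (−2.71 ± 0.26 and −2.88), the relaxin family receptor Rxfp3 (−2.70 ± 0.56 and −2.91) and the desmosomal cadherin Dsc3 (−2.58 ± 0.25 and −2.65). Falls of under 2.5 were those of Kirrel2 (−2.49 ± 0.39 and −2.43), the ephrin receptor Epha8 (−2.41 ± 0.51 and −1.97), Insrr (−2.37 ± 0.21 and −2.49), Gng4 (−2.33 ± 0.15 and −2.27) and the vesicular glutamate transporter Slc17a8 (−2.26 ± 0.45 and −2.25). Their FDR was at most 0.0131, except for Kcnh5 (0.0429). Epha8 did not pass within the high-rRNA libraries (FDR 0.139) or with the replicate number as a block (0.057). The Kcnh5 call was lost without cranial control 2 (FDR 0.0687), cKO 1 (0.107), cKO 2 (0.106), cKO 3 (0.0714) or cKO 4 (0.0958). It was also lost in 1 fit of all 16 libraries (0.0864), with the 18S rRNA term (0.0803) and with the replicate number as a block (0.065).

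Within the high-rRNA libraries 1514 of 21010 genes passed, 838 upward and 676 downward, so that 55.4% of calls were higher against 44.5% over all 8 libraries. With all 16 libraries in 1 fit, 31.4% of the cranial calls were higher. Of the 2140 genes, 1203 passed again within the high-rRNA libraries, and all 2140 kept their sign there. The count fell to 941 without cranial cKO 4, 1007 without cKO 2, 1106 without cKO 3, 1231 without control 4 and 1248 without control 3, and rose to 3258 without control 1.

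The duct mesenchyme list passed downward in the cranial cKO libraries but went both ways, with 8 of 17 tested members down and 4 up (9 and 5 adjusted over the list alone, camera FDR 0.0189, adjusted p = 0.473 with an estimated correlation). Within the high-rRNA libraries 9 fell and 4 rose (camera FDR 0.0474). Beside Osr2 and Foxl2, the members that fell included the AMH receptor Amhr2 (−0.67 ± 0.08 and −0.63 within the high-rRNA libraries) and the Wnt ligand Wnt5a (−0.49 ± 0.06 and −0.52). Wif1, named above among the rising genes, is a member that rose, by more than any of these fell. Retinoic acid genes fell too, 6 of 12 and none up (6 and 0 over the list alone, camera FDR 0.0168, adjusted p = 0.398 with an estimated correlation, and camera FDR 0.00517 within the high-rRNA libraries). Aldh1a2, which makes retinoic acid, fell from 440 ± 59.3 to 198 ± 7.07 CPM (−1.09 ± 0.07, FDR 1.07e-05, and −0.98). The retinol transporter Stra6 (−0.71 ± 0.07 and −0.70) and the retinoic acid binding protein gene Crabp1 (−0.45 ± 0.07 and −0.43) fell less. Of 13 Wnt feedback targets 8 fell and 1 rose (8 and 3 adjusted over the list alone, camera FDR 0.0392, adjusted p = 0.398 with an estimated correlation, and camera FDR 0.0276 within the high-rRNA libraries, with 6 down and 1 up). Axin2 (−0.40 ± 0.06 and −0.37), Tcf7 (−0.65 ± 0.11 and −0.56) and Notum (−0.64 ± 0.11 and −0.43) fell, and Lgr5, a receptor for R-spondins, rose (0.70 ± 0.09 and 0.70). The Wnt list missed the threshold without cranial control 1 (FDR 0.0826), cKO 2 (0.0515) or cKO 4 (0.0507).

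Some of the Hox genes were lower in the cranial cKO libraries, and most members of both Hox lists did not pass. Of 21 anterior and central Hox genes 5 fell and none rose (6 and 0 adjusted over the list alone, camera FDR 0.0141, adjusted p = 0.398 with an estimated correlation, and camera FDR 7.57e-04 within the high-rRNA libraries), among them Hoxa5 (−0.71 ± 0.11 and −0.57). Of 7 tested posterior Hox genes 3 fell (4 down and 1 up adjusted over the list alone, camera FDR 0.0177, adjusted p = 0.473 with an estimated correlation), and the list did not pass within the high-rRNA libraries (FDR 0.0789). The 3 were Hoxa9 (−1.0 ± 0.14 and −0.76), Hoxa10 (−0.97 ± 0.16 and −0.77) and Hoxc9 (−0.69 ± 0.13 and −0.58), and each passed within the high-rRNA libraries as well. The BMP and TGF-beta list as a whole did not pass (camera FDR 0.966; 2 of 20 up and 2 down, 3 and 4 adjusted over the list alone), although Bmp7 fell from 52.6 ± 6.25 to 25.1 ± 1.93 CPM (−1.01 ± 0.09 and −0.96). Hand2, a transcription factor of mesenchyme and of sympathetic neurons, also fell (−1.21 ± 0.14 and −1.12).

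Extracellular matrix genes rose in the cranial cKO libraries, 19 of 26 members against 2 down (21 and 2 adjusted over the list alone, camera FDR 2.23e-08, adjusted p = 0.398 with an estimated correlation), and 17 against 3 within the high-rRNA libraries (5.58e-09). Collagen I rose in both chains, Col1a1 from 5157 ± 288 to 7672 ± 287 CPM (0.63 ± 0.05 and 0.58) and Col1a2 (0.51 ± 0.05 and 0.52). Periostin (Postn) rose from 794 ± 53.4 to 1249 ± 54.1 CPM (0.72 ± 0.06 and 0.73). Col5a2 rose by a similar amount (0.58 ± 0.06 and 0.62). Macrophage markers rose, 7 of 14 and none down (8 and 0 adjusted over the list alone, camera FDR 2.55e-04, adjusted p = 0.333 with an estimated correlation, and camera FDR 1.06e-05 within the high-rRNA libraries), among them the CSF1 receptor Csf1r (0.68 ± 0.08 and 0.70), Adgre1 (0.83 ± 0.13 and 0.97) and Mrc1 (0.45 ± 0.08 and 0.47). Endothelial markers rose in the same number, 7 of 14 and none down (8 and 0 adjusted over the list alone, camera FDR 0.00559, adjusted p = 0.473 with an estimated correlation, and camera FDR 7.57e-04 within the high-rRNA libraries), with VE-cadherin (Cdh5, 0.56 ± 0.09 and 0.50) and Pecam1 (0.55 ± 0.11 and 0.47) as examples. Without cranial control 1 the endothelial list missed the threshold (FDR 0.0506). The cell cycle list passed downward, with 3 of 25 members down and none up (3 and 0 adjusted over the list alone, camera FDR 4.94e-04, adjusted p = 0.473 with an estimated correlation, and camera FDR 0.0276 within the high-rRNA libraries), with the replication clamp Pcna among them (−0.43 ± 0.07 and −0.40). That number of calls is near the share over all tested genes (2140 of 19455). Ccnb2, also among the 3, did not pass within the high-rRNA libraries (FDR 0.265). It was lost too without cranial control 3 (0.0902), control 4 (0.104), cKO 1 (0.0961), cKO 2 (0.112) or cKO 4 (0.0867). The remaining call, Tyms, was lost without cranial cKO 2 (0.0606), cKO 3 (0.0706) or cKO 4 (0.0792).

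Epithelial genes of the ducts showed no shift of the whole list in the cranial region. Of 20 duct epithelium genes 1 rose and 3 fell (3 and 6 adjusted over the list alone, camera FDR 0.966), with a median change of 0.03 and a mean of 0.03 although the test's direction was downward. The keratin Krt8 fell from 103 ± 13.2 to 70.6 ± 9.08 CPM (−0.48 ± 0.10, FDR 0.0126, and −0.39 within the high-rRNA libraries), and missed the threshold without cranial cKO 2 (FDR 0.0526) or cKO 4 (0.0535). The Müllerian duct list (2 of 9 up, 0 down; 3 and 1 adjusted over the list alone, camera FDR 0.32) and the GATA list (1 of 8 up, 1 down; 1 and 1, camera FDR 0.399) did not pass. Gata6 stood at 0.29 ± 0.12 (FDR 0.148) and passed within the high-rRNA libraries (0.54, FDR 1.46e-05). The Wolffian duct and nephric tubule list passed upward (camera FDR 0.0392, adjusted p = 0.398 with an estimated correlation, and camera FDR 0.0397 within the high-rRNA libraries), with 0 of 13 members past the FDR over all genes and 0 adjusted over the list alone. Its members with the smallest p were Cdh16 (0.45 ± 0.13, FDR 0.0533, and 0.19) and Pax2 (0.49 ± 0.16, FDR 0.063, and 0.27). That list missed the threshold without cranial control 1 (FDR 0.0506), control 2 (0.114) or cKO 2 (0.102).

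Hypoxia and glycolysis genes fell (6 of 16 down, 0 up; 6 and 0 adjusted over the list alone, camera FDR 0.0258, adjusted p = 0.561 with an estimated correlation), with Higd1a as an example (−0.67 ± 0.12 and −0.63 within the high-rRNA libraries). The list did not pass within the high-rRNA libraries (FDR 0.387), nor without cranial control 4 (0.0551) or cKO 1 (0.0992). Immediate early genes passed downward with 0 of 14 members past the FDR over all genes and 4 adjusted over the list alone (camera FDR 0.0392, adjusted p = 0.668 with an estimated correlation). They did not pass within the high-rRNA libraries (FDR 0.298), nor without cranial control 2 (0.221), control 3 (0.326), cKO 1 (0.109), cKO 3 (0.0697) or cKO 4 (0.0531).

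**Figure D2:**
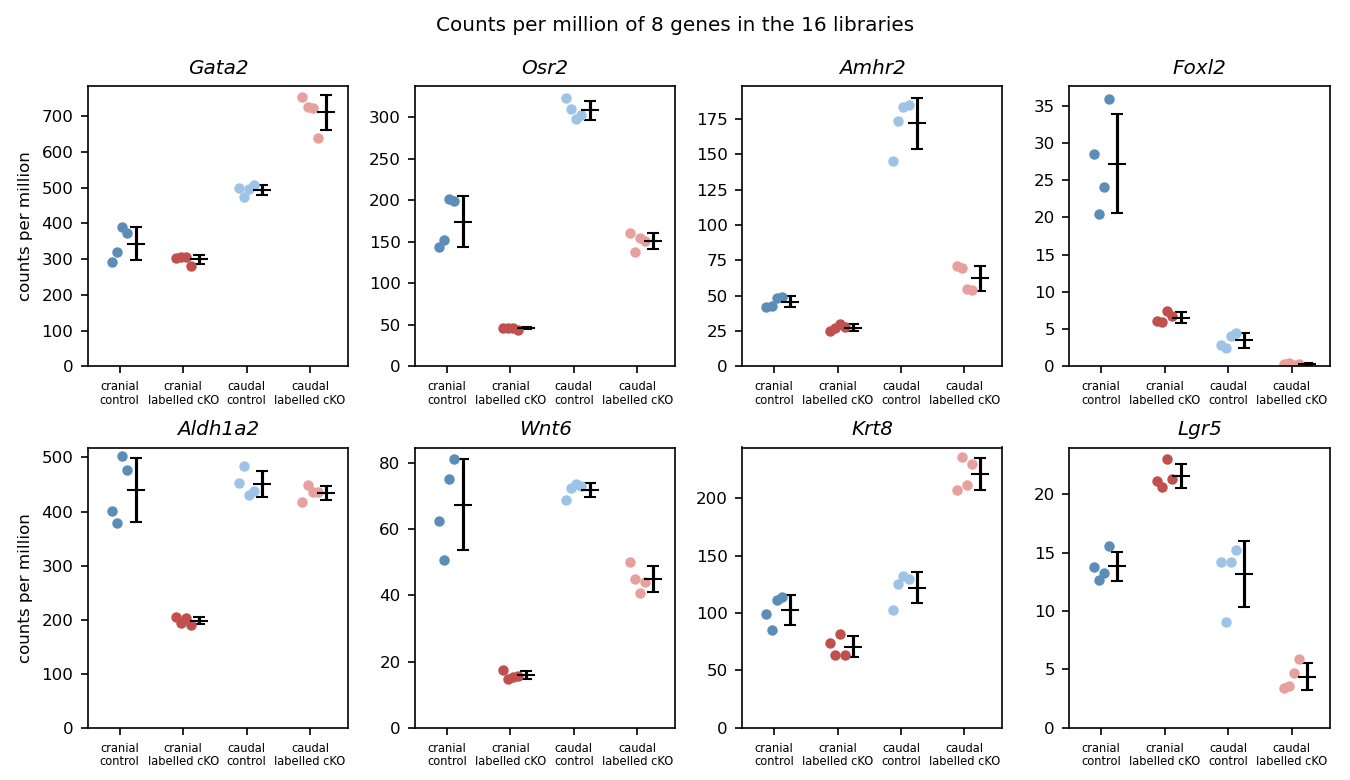
Counts per 1e6 (CPM) of Gata2, Osr2, Amhr2, Foxl2, Aldh1a2, Wnt6, Krt8 and Lgr5 by region and genotype label. Each point is a library and the bars are the mean ± SD (n = 4). All 4 labelled cKO libraries lie below all 4 controls for Osr2, Amhr2 and Foxl2 in both regions, and above the caudal controls for Krt8.

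In the caudal mesonephros 1436 of 18199 tested genes changed with the cKO label, 879 upward and 557 downward, and 407 changed at least 2-fold. Caudal controls 1 and 2 stood apart from controls 3 and 4. Chi-square over its degrees of freedom was 25.1 between 1 and 2, 11.5 between 3 and 4, and 54.8 to 80.6 across. Mitochondrial genes held 2.43% and 2.31% of counts in controls 1 and 2, and 1.46% and 1.51% in 3 and 4. The source of that difference was not tested. Corin, a serine protease that activates natriuretic peptides, rose from 0.286 ± 0.127 to 19.6 ± 2.69 CPM (6.09 ± 0.25, FDR 3.68e-09). The forkhead gene Foxl1 rose from 0.401 ± 0.175 to 11.3 ± 1.57 CPM (4.80 ± 0.28, FDR 6.79e-08). The neuropeptide gene Nts rose from 2.62 ± 1.39 to 40.1 ± 5.37 CPM (3.94 ± 0.28, FDR 5.55e-07) and Lrriq1 from 1.26 ± 0.343 to 16.2 ± 0.754 CPM (3.67 ± 0.21, FDR 4.86e-08). Among falling genes, Sall1, a zinc finger transcription factor of kidney mesenchyme, went from 97.4 ± 16.3 to 14.4 ± 4.5 CPM (−2.76 ± 0.18, FDR 2.53e-07). The chemokine Cxcl14 went from 45.3 ± 8.37 to 4.14 ± 1.35 CPM (−3.45 ± 0.21, FDR 9.03e-08).

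The other rising genes of the naming rule were the forkhead genes Foxq1 (5.32 ± 0.74) and Foxa1 (4.32 ± 0.77), Cbln2 (3.32 ± 0.51) and Pkp1, a desmosomal plaque gene (3.56 ± 0.91). Another 2 are uncertain: Sprr2g (4.01 ± 0.73), which belongs to a family of near-identical genes, and Dlx6os1 (3.41 ± 0.22), an antisense gene counted without a stated strand. The other falling genes were Ttc29 (−4.23 ± 0.66), the apelin receptor ligand Apela (−4.08 ± 0.52), the calcium sensor Vsnl1 (−4.01 ± 0.40), Clic6 (−3.67 ± 0.48), Foxl2 (−3.43 ± 0.39), Ap3b2 (−3.26 ± 0.32), Tafa1 (−3.10 ± 0.45) and the lipoxygenase Alox12b (−2.84 ± 0.32). Their FDR was at most 0.00256, except for Pkp1 (0.0241), whose call was lost without caudal cKO 1 (FDR 0.0639), cKO 2 (0.0772) or cKO 4 (0.0965), with the DESeq2 Wald test (0.052) and with limma-voom (0.0617). The count of 1436 fell to 931 without caudal cKO 2 and 953 without cKO 4.

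Duct epithelium genes rose in the caudal cKO libraries, 12 of 20 against 1 down (13 and 1 adjusted over the list alone, camera FDR 4.93e-07, adjusted p = 0.227 with an estimated correlation). The keratin Krt8 rose from 122 ± 13.6 to 221 ± 13.7 CPM (0.85 ± 0.10, FDR 4.96e-05). Krt7 rose from 46.6 ± 2.10 to 76.9 ± 7.58 CPM (0.72 ± 0.10), and the tight junction genes Cldn4 (1.20 ± 0.15) and Cldn6 (0.76 ± 0.10) rose with them. GATA factor genes rose, 4 of 8 and none down (4 and 1 adjusted over the list alone, camera FDR 0.00133, adjusted p = 0.196 with an estimated correlation), with Gata3 (1.59 ± 0.23) and Gata6 (0.83 ± 0.09) beside Gata2. Mesothelial genes rose, 7 of 10 and none down (9 and 1 adjusted over the list alone, camera FDR 1.58e-05, adjusted p = 0.196 with an estimated correlation), among them the mucin Muc16 (1.44 ± 0.21), Upk3b (0.82 ± 0.13) and mesothelin (Msln, 1.11 ± 0.21). Genes of the urogenital sinus and urothelium rose, 3 of 8 and none down (5 and 0 adjusted over the list alone, camera FDR 1.98e-04, adjusted p = 0.22 with an estimated correlation). They were Foxa1, Gata3 and Krt14, which went from 8.45 ± 2.94 to 20.7 ± 1.82 CPM (1.29 ± 0.21). The Müllerian duct list did not pass (2 of 10 up, 1 down; 4 and 1 adjusted over the list alone, camera FDR 0.115). Nor did the Wolffian duct list (2 of 11 up, 3 down; 4 and 3, camera FDR 0.801), in which Etv4, a target of FGF and GDNF signalling, fell (−1.25 ± 0.12).

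The duct mesenchyme list went both ways in the caudal region, with 4 of 18 members up and 7 down (5 and 8 adjusted over the list alone, camera FDR 0.115). Amhr2 fell from 172 ± 18.2 to 62.2 ± 9.10 CPM (−1.47 ± 0.12, FDR 1.29e-06) and Osr2 from 308 ± 11.5 to 151 ± 9.35 CPM (−1.03 ± 0.08, FDR 1.29e-06), whereas the proteoglycan Dcn rose (0.71 ± 0.08). The list of AMH-response genes rose, 6 of 14 against 1 down (6 and 2 adjusted over the list alone, camera FDR 0.0288, adjusted p = 0.227 with an estimated correlation). Its rising members included the transcription factors Sp7 (1.13 ± 0.13) and Msx2 (0.81 ± 0.09) and the signal transducer Smad9 (1.05 ± 0.14). The member that fell was the receptor Amhr2. The list shares Id1, Id2 and Id3 with the BMP and TGF-beta list, so its rise does not by itself show a response to AMH. The AMH-response list missed the threshold without caudal control 1 (FDR 0.0787) or cKO 3 (0.0664). BMP and TGF-beta genes rose, 8 of 20 against 1 down (10 and 1 adjusted over the list alone, camera FDR 0.00125, adjusted p = 0.196 with an estimated correlation), with Bmp5 (1.77 ± 0.20), Bmp4 (0.89 ± 0.20) and the target Id2 (0.41 ± 0.08). The Hedgehog list, which holds co-receptor genes beside targets, rose, with 4 of 10 up and none down (6 and 1 adjusted over the list alone, camera FDR 0.0118, adjusted p = 0.272 with an estimated correlation). Among them were Ptch1 (0.60 ± 0.13) and the co-receptor Boc (0.41 ± 0.08). The call of Gas1 was lost without caudal cKO 2 (FDR 0.0585). That of Hhip was lost without caudal cKO 1 (0.0683) or cKO 4 (0.117) and with limma-voom (0.0629). Wnt feedback targets did not pass as a list (2 of 13 up, 5 down; 2 and 6 adjusted over the list alone, camera FDR 0.116), with a median of 0.05 and a mean of −0.05. Axin2 (−0.60 ± 0.08), Tcf7 (−0.86 ± 0.11), Nkd2 (−0.75 ± 0.08) and Lgr5 (−1.58 ± 0.21) were among those that fell.

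Posterior Hox genes fell in the caudal cKO libraries, 7 of 13 and none up (8 and 0 adjusted over the list alone, camera FDR 5.65e-05, adjusted p = 0.272 with an estimated correlation). Hoxa10 fell from 498 ± 25.6 to 339 ± 14.8 CPM (−0.55 ± 0.08) and Hoxa11 from 149 ± 33.4 to 72.3 ± 5.17 CPM (−1.04 ± 0.13). Hoxd9 (−0.74 ± 0.11) and Hoxd10 (−0.94 ± 0.15) fell beside them. Cell cycle genes fell, 5 of 25 and none up (13 and 0 adjusted over the list alone, camera FDR 4.93e-07, adjusted p = 0.227 with an estimated correlation), with Ube2c (−0.55 ± 0.10), Aurkb (−0.43 ± 0.08) and Pcna (−0.45 ± 0.09). The p53 list had 5 of 22 up and none down (5 and 0 adjusted over the list alone) and did not pass as a group (camera FDR 0.0529). Its rising members included the cell cycle inhibitor Cdkn1a (0.67 ± 0.14) and Trp53inp1 (0.86 ± 0.14). Extracellular matrix genes rose, 9 of 26 against 2 down (11 and 2 adjusted over the list alone, camera FDR 0.00125, adjusted p = 0.491 with an estimated correlation), including Postn (1.17 ± 0.14). The 2 that fell were abundant: versican (Vcan) went from 1453 ± 143 to 577 ± 64.7 CPM (−1.33 ± 0.10) and fibronectin (Fn1) from 2123 ± 380 to 1082 ± 52.8 CPM (−0.97 ± 0.11). Macrophage markers rose with 2 of 14, Lyz2 (0.87 ± 0.14) and Mrc1 (0.51 ± 0.11), and none down (2 and 0 adjusted over the list alone, camera FDR 0.0118, adjusted p = 0.227 with an estimated correlation), and missed the threshold without caudal control 4 (FDR 0.0744). The estrogen receptor gene Esr1 fell (−0.50 ± 0.10), and its list of 6 did not pass (2 up, 1 down; 2 and 1 adjusted over the list alone, camera FDR 0.692). In the controls, posterior Hox and cell cycle genes were higher caudally, and matrix, macrophage, mesothelial and BMP genes higher cranially, as given below. Each of these lists thus moved toward the cranial side in caudal cKO libraries. The duct epithelium and AMH-response lists, also higher caudally in the controls, rose and so went the other way. Caudal cKO pieces cut at a more cranial level cannot be told apart here from an effect of the genotype on the lists that moved toward the cranial side. In the cranial cKO libraries posterior Hox and cell cycle lists also passed downward, and matrix and macrophage lists upward. Mesothelial and BMP lists did not pass there, and anterior and central Hox genes (down) and endothelial genes (up) moved toward the caudal side. A more cranial level of the cranial cKO pieces was not tested.

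**Figure D3:**
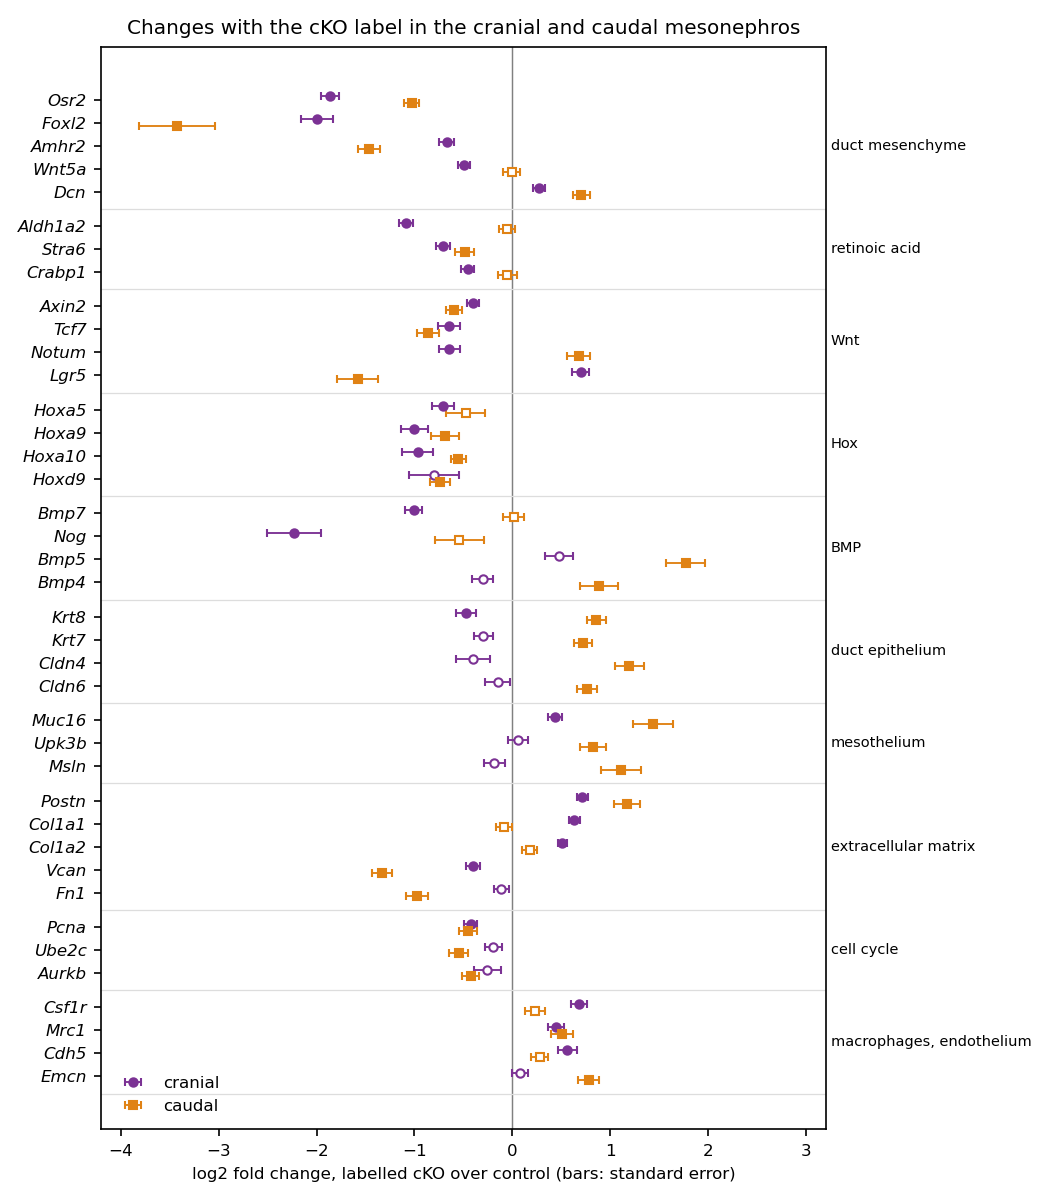
Log2 fold changes of labelled cKO over control ± SE for members of the gene lists, in the cranial (circles) and caudal (squares) mesonephros, with open symbols for an FDR of 0.05 or more. Osr2, Foxl2 and Amhr2 lie below 0 in both regions. Krt8 lies at −0.48 cranially and 0.85 caudally.

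The effects of the cKO label differed between the regions. A test of the interaction of region and genotype, over all 16 libraries, called 717 of 21252 genes, of which 215 changed more upward in the cranial region and 502 more upward in the caudal region. With DESeq2 size factors in place of TMM there were 731 calls and the share on the cranial side was 44.3% against 30.0%. The genes of the naming rule were Shox2 (4.67 ± 0.53), Kynu (4.24 ± 0.86), the ryanodine receptor Ryr3 (3.54 ± 0.61), the relaxin receptor Rxfp1 (3.15 ± 0.81) and Ap3b2 (2.98 ± 0.41) on the cranial side. On the caudal side they were Corin (−5.70 ± 0.54), Dlx3, Fgf14, Rasgrf1 and Foxl1 (−3.98 ± 0.74). The fitted values of Dlx3, Fgf14 and Rasgrf1 rest on a group with 2, 3 and 4 counts and depend on the prior count. Dlx3 stood at 6.12 ± 0.942 CPM in caudal controls, 20.4 ± 4.26 in caudal cKO libraries and 0.181 ± 0.232 and 0.0206 ± 0.0412 in the cranial groups. Fgf14 went from 0.0208 ± 0.026 to 0.699 ± 0.179 CPM and Rasgrf1 from 0.0291 ± 0.0336 to 0.574 ± 0.23 CPM in the caudal region, and stood at 1.71 ± 0.347 and 1.80 ± 0.234 CPM, and at 2.90 ± 0.322 and 2.98 ± 0.404 CPM, in cranial controls and cKO libraries. With 18S rRNA content as a term 464 genes passed, 167 on the cranial side and 297 on the caudal side, and 400 of the 717 passed again. Dlx3 was not among them (FDR 0.596), and it also missed the threshold without cranial control 4 (0.0651). Rxfp1 missed it without cranial cKO 3 (FDR 0.0729) or cKO 4 (0.0708), caudal control 1 (0.0567) or control 2 (0.0717), or caudal cKO 1 (0.0563), cKO 2 (0.0728) or cKO 3 (0.0616). The count was 464 without caudal cKO 2, 467 without cranial control 4 and 475 without cranial cKO 4.

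Between the regions, 8 of 20 duct epithelium genes changed more upward in the caudal region and none in the cranial region (12 and 2 adjusted over the list alone, camera FDR 3.62e-05, adjusted p = 0.484 with an estimated correlation). The mesothelial list (7 of 10; 8 adjusted over the list alone, camera FDR 3.13e-05, adjusted p = 0.263 with an estimated correlation) and the BMP list (6 of 20 against 1; 10 and 1, camera FDR 5.09e-04, adjusted p = 0.263 with an estimated correlation) differed the same way. So did the urogenital sinus list, by 1 of 9 members past the FDR (2 adjusted over the list alone, camera FDR 9.49e-05), which held with an estimated correlation (adjusted p = 0.0264). Chosen after their values were seen, the interaction values of single genes were −0.72 ± 0.12 for Gata2 (FDR 9.33e-04), −1.39 ± 0.15 for Krt8, −1.65 ± 0.24 for Cldn4, −1.09 ± 0.12 for Aldh1a2 and −1.08 ± 0.15 for Bmp7. They were −1.40 ± 0.16 for Wnt6, −0.89 ± 0.14 for Osr2, −1.09 ± 0.14 for the neuronal gene Stmn2, 2.23 ± 0.24 for Lgr5 and 0.74 ± 0.15 for Amhr2, with an FDR of at most 0.00581. Aldh1a2 and Bmp7, which fell in the cranial region, stood at −0.05 ± 0.08 (FDR 0.781) and 0.01 ± 0.11 (FDR 0.962) in the caudal region.

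Other genes moved alike in both regions. Across the 17440 genes tested in both, the cranial and caudal log2 fold changes correlated with a Pearson r of 0.211 (jackknife SE 0.091) and a Spearman rho of 0.228, where genes are not independent replicates and the 2 fits share no library. Over genes with a mean log2 CPM of at least 3 the Pearson r was 0.373. Of the genes called in both, 224 rose in both regions against 45.9 expected of independent calls, 145 fell in both against 36.5, and 45 went opposite ways. With the cranial fit within the high-rRNA libraries, r was 0.202, and 243 genes rose and 120 fell in both. Ccn3, Oxtr, Lrrc55 and Sostdc1 were higher in the cKO libraries of both regions. The caudal levels went from 4.45 ± 1.26 to 20.2 ± 2.38 CPM for Ccn3 and from 1.24 ± 0.414 to 7.66 ± 1.08 CPM for Sostdc1.

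In the controls, the regions differed in 7270 of 21252 genes, 3474 higher in the cranial mesonephros and 3796 higher in the caudal. Posterior Hox genes were caudal, 12 of 13 against 1 (12 and 1 adjusted over the list alone, camera FDR 7.76e-12, adjusted p = 0.0868 with an estimated correlation). Hoxa10 stood at 15.3 ± 3.66 CPM cranially and 498 ± 25.6 CPM caudally. The caudal to cranial ratio of summed counts, scaled to library size, was 979 for Hoxc11 (exact interval 419 to 3016), 527 for Hoxd11 (360 to 808), 286 for Hoxd12 (131 to 782) and 262 for Hoxa11 (212 to 329). It was 199 for the noncoding gene Hotair (77.4 to 732), 169 for Hoxd13 (65.8 to 623) and 101 for Hoxd10 (85.3 to 120). It was 95.4 for the homeobox gene Dlx6 (51.6 to 200) and 82.1 for the growth factor Gdf7 (57.0 to 123), and 242 for Hoxa11os (160 to 387), an antisense gene that is uncertain without a stated strand. Anterior and central Hox genes were higher in the cranial region in 10 of 21 and lower in 6 (11 and 6 adjusted over the list alone, camera FDR 0.0103, adjusted p = 0.364 with an estimated correlation), with Hoxc4, Hoxc5, Hoxc6 and Hoxc8 up by 1.51 ± 0.10, 2.19 ± 0.12, 2.24 ± 0.12 and 3.69 ± 0.20. Within the libraries of low 18S rRNA, which leave cranial controls 3 and 4 against 4 caudal controls, 5490 genes passed, 2776 and 2714, with camera FDR 3.82e-13 for posterior and 0.0445 for anterior and central Hox genes.

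Among genes higher in the cranial controls, the nuclear receptor Hnf4a was at least 146-fold higher, Keg1 at least 153-fold and Glyat at least 80.3-fold, each with 0 caudal counts. The ratio was 227 for Epyc (62.5 to 1879) and 118 for Clec18a (40.1 to 575). It was 103 for Rasgrf1 (39.9 to 380), 89.2 each for the adrenal and gonadal nuclear receptor Nr0b1 and for Cnmd (34.6 to 329), and 77.5 for Fgf14 (26.2 to 378). Caudal levels of these 9 genes were at most 4 counts over the group, and the intervals cover counting error only.

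Of 20 duct epithelium genes 14 were higher caudally and 2 cranially (15 and 2 adjusted over the list alone, camera FDR 3.4e-04, adjusted p = 0.319 with an estimated correlation, and camera FDR 0.00204 within the low-rRNA libraries), with Pax2 (−2.07 ± 0.15, cranial over caudal), Esrp1 (−1.81 ± 0.15) and Cldn7 (−1.32 ± 0.12) on the caudal side and Krt7 (1.15 ± 0.10) on the cranial side. Müllerian duct genes were caudal in 7 of 10 and cranial in 1 (7 and 1 adjusted over the list alone, camera FDR 5.65e-04, adjusted p = 0.132 with an estimated correlation, and camera FDR 3.47e-04 within the low-rRNA libraries), among them Msx1 (−3.93 ± 0.14), Dlx5 (−3.40 ± 0.13) and Wnt7a (−1.73 ± 0.15). Wolffian duct genes were caudal in 7 of 14 and cranial in 1 (7 and 1 adjusted over the list alone, camera FDR 0.0275, adjusted p = 0.348 with an estimated correlation, and camera FDR 0.0291 within the low-rRNA libraries), with Etv4 (−3.93 ± 0.21) and Etv5 (−2.46 ± 0.16). That list missed the threshold without caudal control 4 (FDR 0.0755). The duct mesenchyme list did not pass (6 of 18 each way; 6 and 7 adjusted over the list alone, camera FDR 0.761). The AMH-response list was caudal in 9 of 14 (9 adjusted over the list alone, camera FDR 5.76e-04, adjusted p = 0.132 with an estimated correlation, and camera FDR 0.00581 within the low-rRNA libraries), with Amhr2 at 45.7 ± 3.85 CPM cranially and 172 ± 18.2 CPM caudally. Gata2 was lower cranially (−0.54 ± 0.08, FDR 2.86e-05, and −0.40 within the low-rRNA libraries), while Gata4 (2.57 ± 0.26), Gata6 (1.31 ± 0.12) and the GATA cofactor Zfpm2 (2.55 ± 0.14) were higher. The GATA list did not pass (3 of 8 each way; 3 and 3 adjusted over the list alone, camera FDR 0.466). Dcn stood at 1571 ± 190 CPM cranially and 343 ± 25.4 CPM caudally. All 25 cell cycle genes were higher caudally (25 adjusted over the list alone, camera FDR 1.43e-17, adjusted p = 0.0868 with an estimated correlation, and camera FDR 1.05e-14 within the low-rRNA libraries), as were 11 of 14 endothelial genes (11 adjusted over the list alone; 3.81e-07, adjusted p = 0.132 with an estimated correlation, and camera FDR 1.31e-06 within the low-rRNA libraries). Mesothelial genes were cranial in 9 of 10 (1 caudal; 9 and 1 adjusted over the list alone; 4.14e-06, adjusted p = 0.132 with an estimated correlation, and camera FDR 1.29e-06 within the low-rRNA libraries) and macrophage genes in 13 of 14 (13 adjusted over the list alone; 2.65e-08, adjusted p = 0.0406 with an estimated correlation, and camera FDR 9.14e-08 within the low-rRNA libraries).

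**Figure D4:**
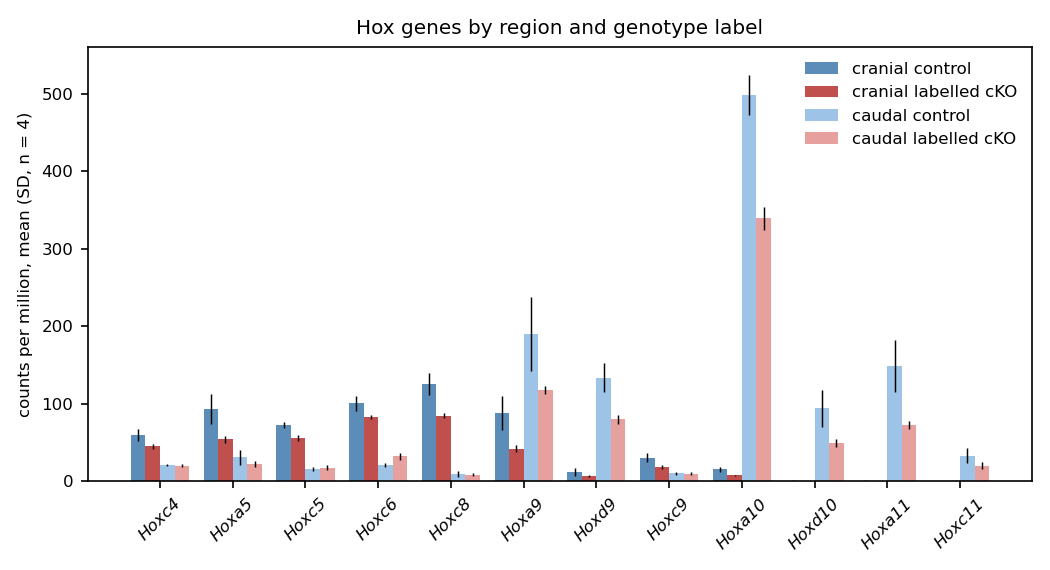
Counts per 1e6 (CPM) (mean, error bars SD, n = 4) of 12 Hox genes in cranial and caudal controls and labelled cKO libraries. Hoxa10 stands at 498 CPM in caudal controls and 339 CPM in caudal labelled cKO libraries.

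In the cKO libraries the regions differed in 8383 of 21252 genes, 3698 higher cranially and 4685 higher caudally. All cranial cKO libraries were high in 18S rRNA and all caudal cKO libraries low, so no value within like libraries could be had. With the effect of 18S rRNA content taken from the cranial controls, 2584 genes passed, 1345 higher cranially and 1239 caudally. With DESeq2 size factors 8263 genes passed, 4431 higher cranially and 3832 caudally, and with the DESeq2 Wald test 9432, 5380 and 4052.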

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

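The tests of the 18S rRNA groups, of sequence beside Gata2, of a wrong label of cranial control 1 alone, of a lower share of mesenchyme and of a more cranial level were chosen after the results were seen, as were 10 of the 20 interaction genes.

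The effect of the cKO label differed between cranial and caudal mesonephros in 717 genes by a test of the interaction. The named values, cranial minus caudal, were 4.67 for Shox2, 4.24 for Kynu, 3.54 for Ryr3, 3.15 for Rxfp1, 2.98 for Ap3b2, −5.70 for Corin and −3.98 for Foxl1. Fitted values of −5.01 for Dlx3, −4.73 for Fgf14 and −4.11 for Rasgrf1 rest on groups with 2 to 4 counts and depend on the prior count. With 18S rRNA content as a term Dlx3 stood at −2.65 (FDR 0.596). Gata2 stood at −0.72, Krt8 at −1.39, Cldn4 at −1.65, Lgr5 at 2.23 and Stmn2 at −1.09. Aldh1a2 stood at −1.09, Bmp7 at −1.08, Wnt6 at −1.40, Osr2 at −0.89 and Amhr2 at 0.74.

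Chance as the source of the counts of genes was tested by refitting other splits of the libraries. In the cranial comparison (2140 genes, at most 0 in the others) and the caudal comparison (1436 and at most 0), 1 of 35 splits gave as many, the real one. The same held for the regions in controls (7270 and at most 727, 1 of 35) and in cKO libraries (8383 and at most 1, 1 of 35). A share of 1 of 35 is the smallest that 35 splits can give, so chance was argued against but not excluded. Splits that mix the groups also put the real difference into the spread, which lowers their counts. For the interaction 2 of 100 drawn splits gave as many genes as the real 717. The other one called 2933 genes. It exchanges the caudal labels and so adds the effects of both regions, which is a structure of the libraries.

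In the cranial region 2140 genes differed by label, while cranial controls 3 and 4 stood apart in 18S rRNA. A whole source in that difference was argued against, since within the 6 high-rRNA libraries 1514 genes passed and at most 4 in the other 14 splits. With 18S rRNA content as a term in the fit of all 8 libraries, 1658 genes passed, 890 upward and 768 downward. Of the 2140, 1294 passed again with that term and 1203 within the high-rRNA libraries. Some of the 937 genes that did not pass within those libraries thus passed with the term. For the others of the 937, batch and genotype cannot be told apart. The median ratio of the change within to the change over all 8 libraries was 0.732 for the 937 and 0.931 for the 1203. Choosing genes by a missed threshold lowers that ratio by itself, so it decides nothing. An effect of the genotype stays open for the 937 genes.

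Gata2 counts did not pass the FDR in cranial cKO libraries, with an estimate below controls (−0.14, FDR 0.264), and were higher in caudal ones. The test of labels written beforehand found 1 library of 16 nearer to the other genotype, cranial control 1 at 0.526 on a scale from control (0) to cKO (1), and so went toward a wrong label. A later test went against it: over 407 caudal genes cranial control 1 stood at −0.183, beside −0.251 to −0.208 in the other cranial controls and 0.191 to 0.229 in cranial cKO libraries. Sequence beside the floxed allele was argued against in the caudal region (p 0.101, odds ratio 0.465, 0.148 to 1.12) and stays open in the cranial region (p 0.115, odds ratio 1.46, 0.891 to 2.29). Transcripts that keep exons outside the floxed part, and Cre acting in part of the cells, stay open and were not tested.

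Duct epithelium genes were higher in caudal cKO libraries, by a mean of 0.462 in log2 CPM, with caudal controls 1 and 2 (5.08 and 5.02) below controls 3 and 4 (5.38 and 5.40). A lower share of mesenchyme raising other cell types alike was argued against, since mesothelium minus endothelium rose by 0.652 (exact p 0.0286, the smallest that 70 splits give) and epithelium minus endothelium by 0.329 (0.0286), the latter mostly over controls 1 (−0.647) and 2 (−0.475), less over 3 (−0.1) and 4 (−0.266). A part of the rise from a fall of duct mesenchyme (−0.214) stays open, since the change of epithelium was 0.161 over macrophages (p 0.429), 0.24 over neurons (0.371), 0.0476 over erythroid cells (0.886), 0.319 over smooth muscle (0.0286) and −0.323 over mesothelium (0.0571), and that of endothelium alone 0.133 (0.114). A more cranial level of the caudal cKO pieces was argued against for the 14 list members that are higher in caudal than in cranial controls, since their mean rose by 0.454 (exact p 0.0286, 8 up and 1 down past the FDR). For the other members it cannot be told apart from an effect of the genotype, since genes lower in cranial controls had a median caudal change of −0.216 against one pair of controls and 0.0322 against the other, and genes higher there 0.435 and 0.160. The mean of the urogenital sinus and urothelium list rose by more than that of duct epithelium, by 1.59 (exact p 0.0286). It went from a low level of −0.364 to 1.22 in log2 CPM. Whether the caudal cKO pieces held more of such tissue was not tested. A larger share of epithelium and an effect of Gata2 stay open.

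Single libraries lay far from the others of their group in 28 of 334 groups of named genes (8.38%) and in 57 of 832 over all groups (6.85%), where chance gives about 1 in 20. In 7 of the 28 the others held 0 counts, so that any count stands apart and that rate does not apply, and without such groups 21 of 324 remain (6.48%). In CPM, with the other 3 libraries in brackets, cranial cKO 4 held 280.8 of Gata2 (303.6 to 307.2) and 43.85 of Osr2 (46.55 to 46.76). Cranial cKO 1 held 1.225 of Slc24a2 (0.8102 to 0.8564) and 0.1837 of Slc17a8 (0.8102 to 0.9249). Lrrc55 stood at 0.4669 in cranial control 2 (1.121 to 1.279) and 7.607 in cranial cKO 3 (5.413 to 5.438). Cranial control 1 held 25.94 of Higd1a (35.01 to 37.02) and 0 of Rxfp1 (0.2935 to 0.3201). Cranial control 3 held 1.195 of Fgf14 (1.829 to 1.964), 7.673 of Dlx5 (5.484 to 5.683) and 0.08386 of Hotair (0). Hoxd13 stood at 0.1556 in cranial control 2 (0) and Dlx3 at 0.08239 in cranial cKO 2 (0).

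Among caudal controls, control 1 held 43.54 of Krt7 (47.44 to 48.13) and 9.941 of Smad9 (8.017 to 8.235). It also held 0.059 of Epyc, 0.0885 of Clec18a and 0.118 of Cnmd, each 0 in the others. Control 2 held 0.2863 of Foxq1 (0 to 0.02693), 9.048 of Lgr5 (14.17 to 15.25), 15.29 of Trp53inp1 (23 to 24.22) and 0.1145 of Nr0b1 (0). Msx2 stood at 50.61 in control 3 (47.18 to 47.7). Among caudal cKO libraries, cKO 4 held 0.6883 of Vsnl1 (0.2027 to 0.2527) and 8.855 of Gata3 (13.65 to 14.79). Caudal cKO 1 held 0.9811 of Ap3b2 (0.5632 to 0.608) and 88.6 of Hoxd9 (77.02 to 77.4), and cKO 3 held 2.229 of Alox12b (0.7582 to 0.9266).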

How the results depend on the processing

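The fits by 18S rRNA content and the alternatives of lists for the interaction and the regions were chosen after the results were seen. No named gene changed sign, and no list that passed changed direction. Lists that did not pass did so in the cranial region with fry (FDR 0.95 for duct epithelium and skeletal muscle, 0.864 for BMP, 0.79 for p53, 0.751 for mesothelium) and within the high-rRNA libraries (0.77 for duct epithelium, p53 and neurons, 0.657 for AMH response, 0.831 for adipocytes, 0.156 for mesothelium, which passed upward there with fry at 0.025). With a library left out, cranial lists whose direction turned at least once ranged in FDR from 0.542 to 0.963 (duct epithelium), 0.777 to 0.983 (BMP), 0.544 to 0.987 (p53), 0.533 to 0.983 (mesothelium), 0.634 to 0.983 (metanephric kidney), 0.244 to 0.972 (erythroid cells), 0.42 to 0.968 (neurons) and 0.482 to 0.981 (skeletal muscle). The caudal ones ranged from 0.202 to 0.975 (anterior and central Hox), 0.377 to 0.983 (immediate early genes), 0.649 to 0.993 (hypoxia) and 0.0512 to 0.85 (mitochondrial mRNAs), and with fry the caudal Wolffian duct list turned (0.992). With the 18S rRNA term 12 of 8383 region calls in cKO libraries and 4 of 7270 in controls passed with the opposite sign, as did 1 in controls within the low-rRNA libraries. The share of called genes that were higher ran from 31.4% to 57.0% in the cranial comparison, 46.7% to 52.5% between regions in controls and 42.6% to 57.0% in cKO libraries, so which direction held more genes depended on the setting. Cranial genes past the FDR numbered 6043 with limma-voom, 1332 with the replicate number as a block, 3508 at an FDR of 0.10 and 204 at 2-fold, and 941 (without cKO 4) to 3258 (without control 1) with a library left out. Also below 2140 by over 1.5 times were 1248 without control 3, 1231 without control 4, 1007 without cKO 2 and 1106 without cKO 3. The caudal count was 407 at 2-fold and 931 (without cKO 2) to 1826 (without control 4), with 953 without cKO 4. The interaction gave 1306 genes with no filter, 1287 with DESeq2, 3417 with limma-voom and 464 with the 18S rRNA term. With a library left out it gave 464 (without caudal cKO 2), 467 (without cranial control 4), 475 (without cranial cKO 4) and at most 1044 (without cranial control 1). The regions differed in 6247 to 7320 genes in controls and 7213 to 8764 in cKO libraries with a library left out, and in 2584 in cKO libraries with the 18S rRNA term. The cause of these shifts was not tested. Gata2 stood at −0.22 to −0.11 cranially and 0.50 to 0.58 caudally with a library left out. The correlation of cranial and caudal changes was 0.373 over genes of mean log2 CPM of at least 3, and 0.142 to 0.228 with a library left out. Of 12 cranial lists 0 passed with an estimated correlation, and 28 lists passed with fry for mixed changes. Of 11 caudal lists 0 passed with an estimated correlation, and 18 with fry by direction and 27 for mixed changes. Replicate numbers did not pair the libraries (correlations of −0.219 to 0.139). Other scaling moved the median of all genes by at most 0.0856.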

Other observations

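Markers of other cell types were tested because a dissected mesonephros could hold them. In the cranial region smooth muscle (3 of 13 up, 1 down, camera FDR 0.399), mesothelium (2 of 10 up, 1 down, 0.984), p53 (2 of 22 up, 2 down, 0.984), ovarian somatic cells (1 of 12 up, 2 down, 0.399) and kidney (1 of 6 up, 0.838) did not pass. Nor did FGF signalling (3 of 15 up, 0.241), Hedgehog response (1 of 10 up, 0.24), AMH response (1 of 14 up, 1 down, 0.558), steroid receptors (1 of 7 up, 0.326), neurons (2 of 15 down, 0.841), cartilage and bone (2 of 6 up, 0.326), heat shock (1 of 10 down, 0.326) and genes beside Gata2 (1 of 21 up, 5 down, 0.326). Camera tests a shift in 1 direction and does not count calls. Called in the cranial region were 15.2% of genes within 5 Mb of Gata2 and 11% of genes elsewhere, so the listed genes beside Gata2 were called more often than both. Several of these calls were not stable. Cnbp (FDR 0.0913) and Hmces (0.18) missed the threshold within the high-rRNA libraries, and Plxna1 with the 18S rRNA term (0.0667). Without cranial control 4, Cnbp (0.0723), Hmces (0.0603) and Plxna1 (0.0817) each missed it. The megalin gene Lrp2 rose (0.93 ± 0.11, and 1.07 within the high-rRNA libraries), as did Fgfr1 (0.34 ± 0.06 and 0.31). Desmin (Des, −0.53 ± 0.08 and −0.42) and Stmn2 (−0.54 ± 0.08 and −0.57) fell. No member passed in the lists of ciliated cells (camera FDR 0.431), germ cells (0.399), steroidogenic cells (0.399), urogenital sinus (0.301), erythroid cells (0.399), skeletal muscle (0.984), adipocytes (0.838) and mitochondrial mRNAs (0.0749).

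In the caudal region smooth muscle (3 of 13 up, camera FDR 0.213), endothelium (3 of 14 up, 1 down, 0.0947), kidney (2 of 4 up, 0.0529), neurons (4 of 13 up, 1 down, 0.643), ovarian somatic cells (2 of 12 down, 0.582) and cartilage and bone (2 of 7 up, 1 down, 0.115) did not pass. Smooth muscle actin (Acta2, 0.85 ± 0.12) and Mylk (0.46 ± 0.09) rose, and so did the endothelial genes Emcn (0.78 ± 0.10) and Tek (0.61 ± 0.12), while Vwf fell (−0.96 ± 0.20). Lrp2 (1.29 ± 0.25) and Stmn2 (0.50 ± 0.11) rose, and Wnt6 (−0.68 ± 0.09) and Hand2 (−0.96 ± 0.11) fell. Lists of FGF signalling (4 of 15 down, camera FDR 0.115), retinoic acid (1 of 10 down, 0.44), anterior and central Hox genes (1 of 21 up, 1 down, 0.721), immediate early genes (2 of 14 up, 0.759), heat shock (1 of 10 up, 2 down, 0.582), hypoxia (2 of 16 up, 1 down, 0.877), adipocytes (1 of 4 up, 0.432) and germ cells (1 of 5 up, 0.382) did not pass either. No member passed in ciliated cells (camera FDR 0.214), steroidogenic cells (0.478), erythroid cells (0.115), skeletal muscle (0.801), mitochondrial mRNAs (0.475) and genes beside Gata2 (0.683).

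The immediate early gene Fos had 176, 4200, 15660 and 1064 counts in cranial controls 1 to 4.

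Between the regions, 3 more lists passed in the interaction, all more upward in the caudal region: anterior and central Hox genes (1 of 21, camera FDR 0.0412), p53 (1 of 22, 0.0387) and hypoxia (2 of 16, 0.0414). None held with an estimated correlation (adjusted p = 0.69, 0.426 and 0.69). With 1 library left out Hox genes missed the threshold in 7 of 16 fits (FDR up to 0.0989), p53 in 3 (0.0645) and hypoxia in 7 (0.0986), and Hox genes (0.129) and hypoxia (0.0929) missed it with fry. In controls, 6 more lists differed between the regions. Matrix (15 of 26 cranial, 4 caudal, camera FDR 0.00101), BMP (12 of 20 cranial, 5 caudal, 0.0388), kidney (4 of 8 cranial, 0.041) and mitochondrial genes (4 of 12 cranial, 0.0308) were cranial. With 1 library left out BMP missed the threshold in 2 of 16 fits (FDR up to 0.0838), kidney in 2 (0.0689) and mitochondrial genes in 3 (0.0951). Wnt targets (8 of 13 caudal, 1 cranial, 0.00326) and FGF signalling (8 of 15 caudal, 4 cranial, 0.0246) were caudal. The adjusted p of these 6 with an estimated correlation was 0.132 to 0.49.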
